A study of Mus musculus with 25 samples.

How the data were processed

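Messenger RNA of 25 samples of the KPC line, a C57BL/6 mouse pancreatic ductal adenocarcinoma cell line, was measured in 5 groups of 5 libraries each. Per the labels' protocols, RNA was taken with the PureLink RNA Mini Kit and libraries were made with the QIAseq UPX 3' Transcriptome kit, which reads the 3' ends of polyadenylated transcripts. The parental line was held for 24 h in complete medium or in glutamine-free medium with 10% dialysed serum, and derivatives carrying a hairpin against luciferase (shLuc) or one of a pair of hairpins against Slug (shSlug1 and shSlug2) were held in glutamine-free medium. Whether the replicates were separate cultures, and on which days they were made, is not given in the sources used here, so the p-values measure only the spread between these samples.

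The authors deposited 1 table of normalised values for 30926 genes, of which 2766 had no count in any library, in CPM, that is counts scaled to the same total in every library. Each column summed to 1e+06, and dividing by the smallest step of a column gave whole numbers for 100% of its values within a tolerance of 0.001, so the read counts behind the table were recovered. The recovered totals ran from 158729 to 549893 counts per library, which makes 1 count worth between 1.82 and 6.30 CPM. Per the submitters' processing notes the genome build was mm10. The aligner, the annotation, the treatment of molecular identifiers, the use of strand and the handling of reads shared by several genes are not given in the sources used here. Genes with close copies or overlapping neighbours, among them the ribosomal protein genes with their processed pseudogenes, the mitochondrial genes with their nuclear copies and Acat2 with its neighbour Acat3, therefore carry an uncertainty that the spread between replicates does not show. Gene IDs were looked up in GENCODE M21 on the same build. Of the 30926 IDs, 30857 were found without their version and 28703 carried the same symbol, and 23 symbols belonged to more than 1 ID. Coordinates are those of this annotation, counted from 1.

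The comparisons were tested with limma-trend (limma 3.58.1, R 4.3.3) on log2(CPM + 1) in a single fit of all 25 libraries with 1 coefficient per group and 20 residual degrees of freedom. The 12473 genes with at least 5 CPM in at least 5 libraries were tested, two-sided, with Benjamini-Hochberg adjustment, and a gene was called at an adjusted p under 0.05. Changes are given as log2 fold changes with the standard error (SE) of the fit and as ratios of group mean CPM. Levels are group means ± SD over 5 libraries. The same comparisons were run on the recovered counts with edgeR's quasi-likelihood test after TMM scaling (edgeR 4.0.16) and with DESeq2 1.42.0. Snai2 and the starvation score were also tested by exact permutation of 5 against 5 libraries, two-sided, for which the smallest possible p is 0.00794. Groups of 5 against 5 have no overlap by chance in 0.794% of genes.

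Gene lists were tested with camera at a preset correlation of 0.01, and again with an estimated correlation, with Benjamini-Hochberg adjustment over the lists of a comparison. Of 28 lists, 23 covered the amino acid response (ATF4 targets), the cytosolic aminoacyl-tRNA synthetases, glutamine metabolism and transport, nucleotide synthesis, mesenchymal and EMT genes, epithelial genes, ERK pathway output, NF-kB and inflammatory genes, the interferon response, the ER unfolded protein response, sterol synthesis, DNA replication, mitosis, glycolysis and hypoxia, the TCA cycle, nuclear-encoded oxidative phosphorylation, autophagy and lysosome, p53 targets, YAP targets, NRF2 targets, cytosolic ribosomal proteins, mitochondrially encoded genes and their protein-coding subset. The other 5 held markers of fibroblasts, leucocytes, endothelium, acinar cells and islets. Lists with fewer than 3 measured members were not tested, which left 24. The lists share members, so their tests are not independent. Members were also counted with the adjustment made over the list alone.

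The genes named in the text were chosen by a rule: Snai2; the 8 risen and the 8 fallen genes with the largest log2 fold change among the calls with a mean of at least 10 CPM in the higher group and no overlap between libraries, leaving out symbols of predicted genes; up to 4 members of each described list with the smallest p; for the overlap of the hairpins, 8 in each direction by the smaller of the log2 changes; and Snai1, Zeb1, Zeb2, Twist1, Vim, Cdh1, Cdh2, Fn1, Epcam, Atf4, Asns, Ddit3, Trib3 and Dusp6 where measured. The comparisons, tests, lists and this rule, and the alternatives named first in the next paragraph, were chosen before the data were examined. Some genes that the rule takes are not reported here.

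The alternatives were pseudocounts of 0.5 and 5, no filter, a minimum of 20 CPM, TMM and quantile scaling, a fit of only the groups compared, the replicate number as a block, edgeR, DESeq2, and leaving out each library in turn. Added after seeing the data were thinning of every library to about 158729 counts (157947 to 159314), CPM recomputed without the mitochondrially encoded genes and Gm42418, a fit without 3 libraries (starved replicate 3, the shallowest, and shSlug1 replicates 4 and 5, with a high mitochondrial share), and the counting of the estimated correlation, planned as a repeat of the list tests, as an alternative. For the overlap of the hairpins, all 15 hairpin libraries, those of shLuc included, were simulated 50 times as unchanged, from 1 mean per gene. In addition, the measured shLuc libraries were split in all 20 ways that gave each hairpin its own controls.

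The procedure was tested on counts simulated from the library sizes and gene means. In the simulated starvation comparison of 11990 genes, limma recovered 38% of genes changed 2-fold and 64% of those changed 4-fold, with 15 false calls among 117, and edgeR recovered 44% and 71% with 7 false calls among 122. In the simulated comparison of shSlug1 with shLuc on 11983 genes, limma recovered 26% and 61% with 3 false calls among 90, and edgeR 31% and 74% with 4 among 109. In a separate simulation of that comparison on 12041 genes, camera called a list of 30 genes raised 1.5-fold and 0 of 27 random lists. The simulated genes varied independently, so this does not show how often camera falsely calls lists of correlated genes. A group at 0 was given the level that 3 counts over the group allow, and ratios that rest on 1 to 3 counts are those of the counts pooled over each group, scaled by the group totals, with a 95% counting interval. These intervals and floors cover counting error only.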

Results

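The 25 libraries of the KPC line, a mouse pancreatic cancer cell line, fell into 5 groups of 5. Parental cells were held in complete medium or in glutamine-free medium (starved). The other 3 groups were starved cells carrying a hairpin against luciferase (shLuc), a first hairpin against Slug (shSlug1) or a second one (shSlug2). Slug is the protein of Snai2, a zinc-finger repressor that drives the epithelial to mesenchymal transition (EMT). The series asked how glutamine depletion acts on Slug and EMT. Group mean totals were 361124 counts per library in complete medium, 285372 in starved cells, 328063 with shLuc, 327321 with shSlug1 and 341035 with shSlug2. The shallowest library was starved replicate 3 with 158729. The mitochondrially encoded share of the counts averaged 24.0%, 25.1%, 19.8%, 20.9% and 16.2% in the same order, with 24.3% and 26.5% in shSlug1 replicates 4 and 5.

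Snai2 (ENSMUSG00000022676.6, chromosome 16, 14705852 to 14709385, plus strand) was 10.5-fold higher in starved than in complete medium, at 79.5 ± 14.5 CPM against 7.54 ± 5.42 (SD, n = 5 each). In the hairpin cells, all of them starved, it stood at 55.9 ± 24.0 CPM with shLuc, 6.09 ± 3.75 with shSlug1 and 4.29 ± 2.89 with shSlug2. The first Slug hairpin thus left it 9.19-fold and the second 13.0-fold below shLuc. The log2 changes were 3.39 (SE 0.55, adjusted p = 1.8e-06) for starvation, -3.27 (SE 0.55, adjusted p = 9.5e-05) for shSlug1 and -3.64 (SE 0.55, adjusted p = 2.0e-05) for shSlug2. The groups did not overlap in any of the 3 comparisons (exact permutation p = 0.00794 each, the smallest possible). Snai2 had 0 counts in shSlug1 replicate 1, which allows up to 7.65 CPM, and in shSlug2 replicate 4, which allows up to 12.4 CPM. Between the hairpins the log2 difference was 0.37 (SE 0.55, exact permutation p = 0.524). Between shLuc and parental starved cells it was -0.58 (SE 0.55, exact permutation p = 0.0952).

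**Figure D1:**
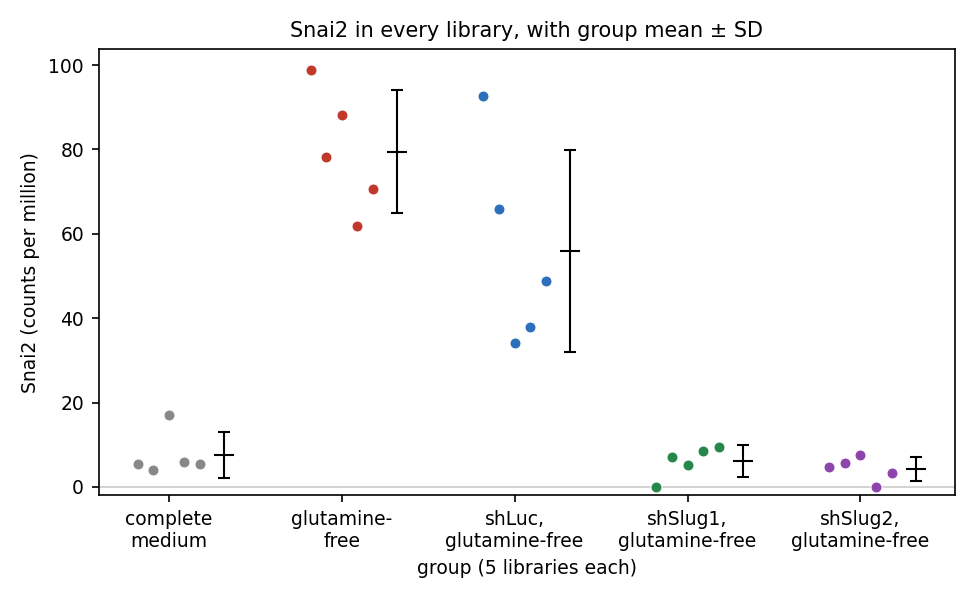
Snai2 level (CPM) in every library of the 5 groups, with the group mean ± SD beside the points. Starved parental libraries sit between 61.8 and 98.8 CPM and shLuc libraries between 34.1 and 92.7, above all libraries in complete medium (3.94 to 17.1) and with either Slug hairpin (0 to 9.45).

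Glutamine starvation, the comparison of parental cells in glutamine-free and complete medium, raised genes of the amino acid response and of ERK pathway output and lowered epithelial, sterol synthesis and mitotic genes. Of the single genes, Gadd45a, a stress-induced growth arrest gene, rose 43.8-fold, from 3.04 ± 3.54 to 133 ± 26.8 CPM (SD, n = 5 each). Ptgs2, which encodes the prostaglandin synthase COX-2, rose 30.03-fold from 19.8 ± 5.22 to 594 ± 70.2 CPM, and Egr1, an immediate early transcription factor, rose 26.3-fold to 134 ± 43.96 CPM. Vsig1, a junction protein of gastric epithelium, fell 35.3-fold from 141 ± 21.8 to 3.99 ± 3.66 CPM. In all, limma called 2799 of 12473 genes, 1341 higher and 1458 lower, with an absolute log2 change of at least 1 in 1742. With edgeR the counts were 3071, 1470 and 1601, and 2555 genes were called by both. The libraries of the groups did not overlap in 1962 genes, against a chance share of 0.794%.

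Further genes with the strongest rise were the kinase gene Plk2 (21.2-fold, to 378 ± 53.4 CPM), the transsulfuration enzyme Cth (21.6-fold, to 70.4 ± 20.96), Bcl2l15 (23.2-fold, to 86.7 ± 28.5) and Gadd45b (13.3-fold, to 144 ± 9.56). Thbd, thrombomodulin, reached 42.9 ± 9.11 CPM from 3 counts in all of complete medium, a ratio of pooled counts of 24.0 with a counting interval of 7.82 to 120.0. Among the falls, Acat2, the cytosolic thiolase of sterol synthesis, fell 22.7-fold from 153 ± 36.7 CPM, the lysosomal acid lipase Lipa 19.1-fold from 59.1 ± 19.3, and the fatty acid elongase Elovl6 17.999-fold from 98.2 ± 10.7. Sh2d4a fell 21.8-fold, Iqgap2 18.7-fold and Tspan13 14.1-fold. The small heat shock protein gene Hspb1 had 21.9 ± 9.19 CPM in complete medium and no count in starved cells, which puts it at least 10.8-fold lower, with the floor at 3 counts over the group.

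The amino acid response was the list with the smallest p. Of its 49 measured members 39 rose and 0 fell (42 and 0 adjusted over the list alone), with a median log2 change of 1.34 (camera adjusted p = 4.0e-43). Atf4, the transcription factor at its centre, rose 4.14-fold from 104 ± 13.1 to 429.6 ± 39.7 CPM, asparagine synthetase Asns 4.15-fold to 416 ± 54.02. Trib3 rose 13.3-fold to 108 ± 17.4 CPM and Ddit3, which encodes CHOP, 5.73-fold to 60.1 ± 26.7. The stress regulator Nupr1 rose 12.7-fold to 608 ± 75.2 CPM and Ppp1r15a, the phosphatase subunit GADD34, 10.5-fold to 227 ± 3.08. Of the 20 cytosolic aminoacyl-tRNA synthetases 11 rose and 1 fell (12 and 1 adjusted over the list alone; adjusted p = 1.5e-11). Lars, Rars, Nars and Tars rose by 2.44-fold to 3.61-fold. Of the 21 genes of glutamine metabolism and transport 8 rose and 3 fell (9 and 5 adjusted over the list alone). Pycr1, a proline synthesis enzyme, rose 6.65-fold, the transaminase Got1 rose 2.24-fold, and Gclm, a subunit of the glutathione synthesis enzyme, fell 2.38-fold. The test of that list gave an adjusted p of 0.038. The call was lost with an estimated correlation (adjusted p = 0.12), with quantile scaling (0.070), without 3 libraries (0.051) and without starved replicate 2 or 3 (up to 0.052).

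Epithelial genes fell, with 1 of 33 measured members higher and 11 lower (1 and 12 adjusted over the list alone), a median of -0.75 and an adjusted p of 1.1e-06. Cdh1, which encodes E-cadherin, fell 2.74-fold from 206 ± 27.2 to 75.1 ± 19.4 CPM (log2 -1.47, SE 0.22, adjusted p = 1.9e-07). The keratins Krt19 and Krt8 fell 5.74-fold and 3.59-fold, and the mucin Muc1 fell 7.84-fold. The mesenchymal and EMT list moved in both directions, with 13 of 26 measured members higher and 7 lower, the same over the list alone, and a median of 0.34 (adjusted p = 0.0047; adjusted p = 0.11 with an estimated correlation). In it the activin subunit Inhba rose 9.90-fold to 202 ± 22.1 CPM, fibronectin (Fn1) 3.20-fold to 324 ± 50.2 and the actin-binding Cald1 2.58-fold to 997 ± 82.9. Zeb2, a zinc-finger repressor of Cdh1, rose 4.88-fold from 13.1 ± 9.09 to 64.0 ± 21.8 CPM (log2 2.45, SE 0.39, adjusted p = 1.3e-06). The mesenchymal markers vimentin (Vim) and S100a4 fell. Vim went from 1336 ± 48.8 to 761 ± 96.2 CPM (log2 -0.82, SE 0.12, adjusted p = 2.5e-07) and S100a4 was 6.52-fold lower. Zeb1 had 63.6 ± 13.2 against 53.6 ± 5.29 CPM (adjusted p = 0.56), and N-cadherin (Cdh2) had 2.71 ± 3.73 against 2.34 ± 1.46 (adjusted p = 0.81). Snai1, Twist1 and Epcam did not reach the minimum level for the test.

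ERK pathway output rose, with 12 of 24 members higher and 2 lower, the same over the list alone (median 0.70, adjusted p = 1.5e-10). Fosl1, an AP-1 factor, rose 5.10-fold to 503 ± 17.5 CPM, the chromatin protein gene Hmga2 3.59-fold to 1178 ± 113 and Myc 3.35-fold to 379.9 ± 20.7. The ERK phosphatase Dusp6 had 158 ± 18.8 against 112 ± 30.3 CPM (adjusted p = 0.030), and its call was lost without control replicate 4 or starved replicates 3 or 5 (adjusted p up to 0.215). YAP targets rose, with 8 of 22 higher and 0 lower, the same over the list alone (adjusted p = 6.3e-06). They included Ankrd1 (2.93-fold), Cyr61 (4.69-fold) and Crim1 (3.07-fold). NF-kB and inflammatory genes had 6 of 18 higher and 2 lower (8 and 4 adjusted over the list alone; adjusted p = 0.034, adjusted p = 0.12 with an estimated correlation). Besides Ptgs2, the feedback inhibitor Tnfaip3 rose 6.44-fold and Nfkb2 2.45-fold, and the alarmin Il33 fell 5.93-fold. Of 20 genes of the p53 target list 6 rose and 3 fell (7 and 3 adjusted over the list alone; adjusted p = 0.030, adjusted p = 0.054 with an estimated correlation). The cell cycle inhibitor Cdkn1a (p21) rose 5.75-fold, Pmaip1 3.38-fold and Trp53inp1 15.4-fold. The median of the p53 list was 0.08 and turned to -0.18 after thinning to 1 depth. Autophagy and lysosome genes had 10 of 48 higher and 3 lower (11 and 3 adjusted over the list alone; adjusted p = 0.028, adjusted p = 0.15 with an estimated correlation). Among the higher ones were the cargo receptor Sqstm1 (2.96-fold), Atp6v0d1 (2.58-fold), Atg12 (3.35-fold) and Wipi2 (2.01-fold). Without 3 libraries the autophagy and NF-kB calls were lost (adjusted p = 0.051 each).

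Sterol synthesis fell as a block, with 0 of 23 members higher and 18 lower (0 and 20 adjusted over the list alone), a median of -2.44 and an adjusted p of 7.9e-16. Squalene epoxidase (Sqle) fell 5.44-fold and Cyp51 6.23-fold. Mitotic genes fell, with 0 of 40 higher and 30 lower (0 and 36 adjusted over the list alone; median -1.36, adjusted p = 1.3e-21). Securin (Pttg1) fell 3.45-fold, the centromere histone Cenpa 4.29-fold, Ube2c 3.01-fold and topoisomerase Top2a 2.85-fold. DNA replication genes had 2 of 41 higher and 12 lower, the same over the list alone (median -0.43, adjusted p = 0.0033, adjusted p = 0.062 with an estimated correlation). The DNA ligase gene Lig1 fell 4.29-fold, Rrm2 1.62-fold and Tyms 1.86-fold. Nucleotide synthesis had 1 of 26 higher and 5 lower (1 and 7 adjusted over the list alone; adjusted p = 0.053). Camera on the recovered counts with edgeR called this list lower (adjusted p = 0.025), while camera in the limma fit with an estimated correlation gave 0.12. NRF2 targets fell, with 3 of 27 higher and 11 lower (3 and 12 adjusted over the list alone; adjusted p = 0.0027). Gsta4 fell 7.62-fold and Prdx1 2.33-fold. Glycolysis and hypoxia genes had 4 of 32 higher and 10 lower (5 and 11 adjusted over the list alone; adjusted p = 0.028, adjusted p = 0.072 with an estimated correlation). They included Aldoa (2.32-fold lower), Tpi1 (2.65-fold lower), Pkm (1.51-fold lower) and Aldoc, which had no count in starved cells and was at least 5.0-fold lower.

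Smaller shifts that lost their calls with an estimated correlation were seen in 3 further lists. Nuclear-encoded oxidative phosphorylation had 5 of 70 higher and 24 lower (6 and 26 adjusted over the list alone; median -0.18, adjusted p = 0.0028, adjusted p = 0.32 with an estimated correlation). In it Uqcrq rose 2.07-fold and Ndufb10 fell 2.34-fold. Cytosolic ribosomal proteins had 3 of 78 higher and 21 lower (3 and 22 adjusted over the list alone; median -0.16, adjusted p = 0.0047, adjusted p = 0.42 with an estimated correlation), with Rps28 down 2.20-fold. The mitochondrially encoded protein genes had 4 of 7 higher and 1 lower (5 and 1 adjusted over the list alone; adjusted p = 0.013, adjusted p = 0.15 with an estimated correlation). Of these mt-Nd4 stood at 3118 ± 78.03 against 1889 ± 303 CPM, and mt-Nd1 lower in this fit (log2 -0.37) but at 0.01 after quantile scaling. Besides nucleotide synthesis, 5 lists were not called. They were the TCA cycle (3 of 31 higher, 7 lower, the same over the list alone; adjusted p = 0.12), the ER unfolded protein response (4 of 25 higher, 9 lower, 5 and 9 adjusted over the list alone; adjusted p = 0.26) and the interferon response (1 of 14 higher, 2 lower, the same over the list alone; adjusted p = 0.58). The others were all mitochondrially encoded genes (4 of 17 higher, 3 lower, the same over the list alone; adjusted p = 0.52) and the fibroblast markers (0 of 3 called, also adjusted over the list alone; median 1.08, or 0 with members at 0 put at their bound; adjusted p = 0.52). Of the markers with fewer than 3 measured members, the leucocyte marker Cd14, named after its value was seen, was lower at 18.9 ± 9.44 against 68.7 ± 11.5 CPM (adjusted p = 0.00024). The 2 endothelial, 1 acinar and 1 islet markers were not called. Of 24 lists tested, 18 were called, 10 higher and 8 lower. With an estimated correlation 8 calls held, those of the amino acid response, the tRNA synthetases, ERK output, YAP targets, epithelial genes, sterol synthesis, mitosis and NRF2 targets. Median, mean and test of the mitochondrially encoded list differed in sign. Camera on the recovered counts with edgeR called the TCA cycle lower (adjusted p = 0.049), while camera in the limma fit with an estimated correlation gave 0.42.

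**Figure D2:**
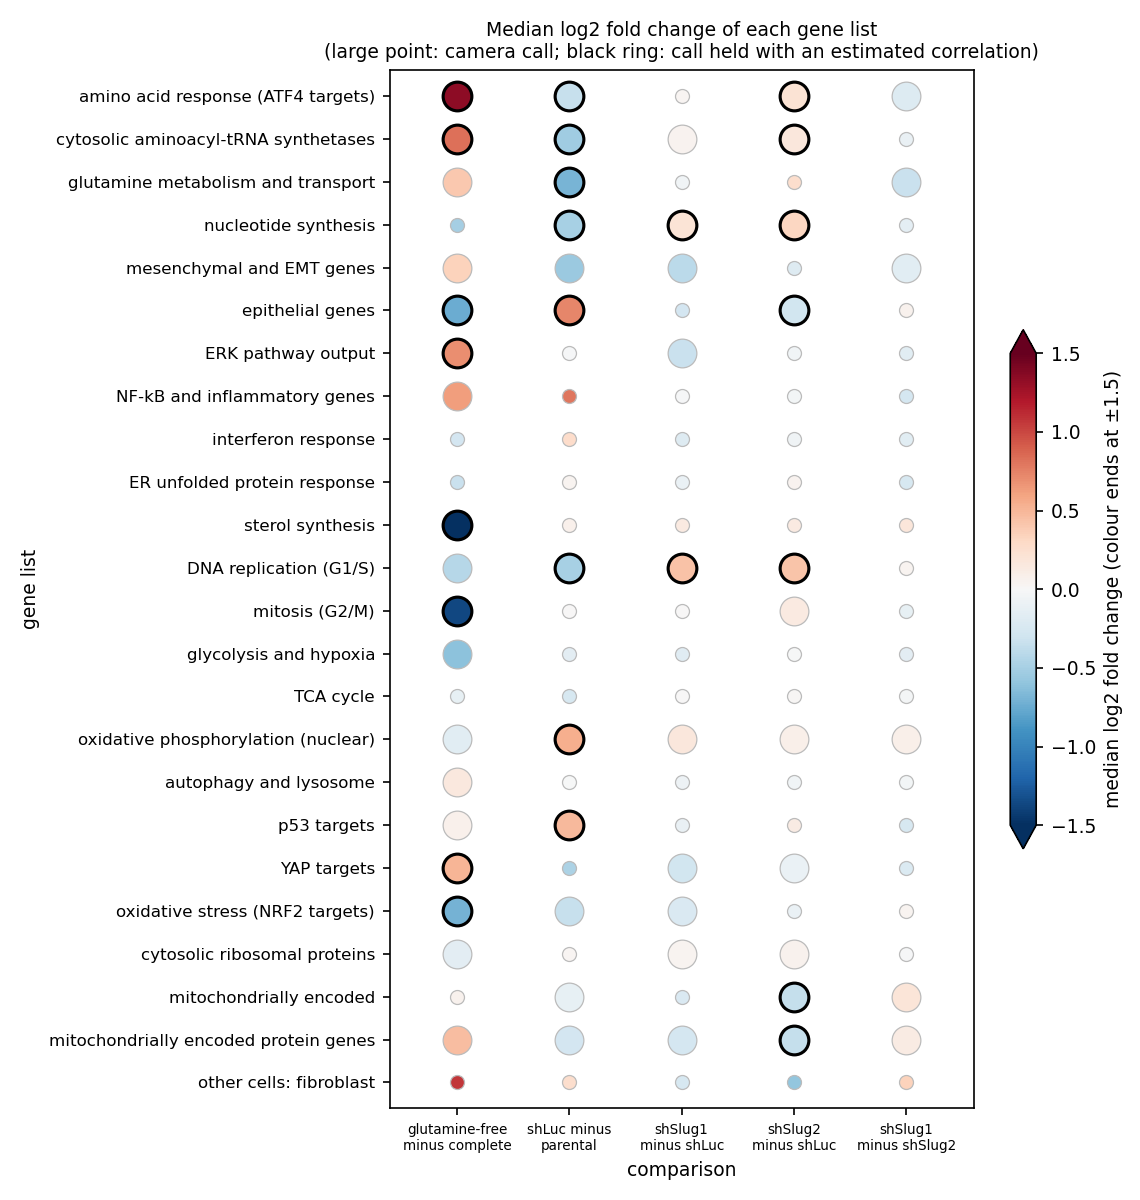
Median log2 fold change (colour) of the 24 tested gene lists in the 5 comparisons, with large points for lists called by camera and a black ring where the call held with an estimated correlation. Sterol synthesis at -2.44 and mitosis at -1.36 were the lowest medians under starvation and the amino acid response at 1.34 was the highest, and DNA replication was lower in shLuc than in parental starved cells (-0.50) and higher with each Slug hairpin than with shLuc (0.44 and 0.43).

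The first Slug hairpin was compared with shLuc in starved cells. No hairpin cells were measured in complete medium, so this comparison cannot show whether a change is specific to glutamine depletion. A change called with this hairpin and not with shSlug2 cannot be assigned to Slug. Besides Snai2, Phldb2 fell from 809 ± 64.7 to 376 ± 56.6 CPM (SD, n = 5 each), the caldesmon gene Cald1 from 689 ± 88.1 to 351 ± 96.9, vimentin (Vim) from 415 ± 106 to 225 ± 20.7 and the matrix gene Fbln2 from 258 ± 67.5 to 121 ± 16.6. Ereg, an EGF receptor ligand, fell 3.96-fold from 73.0 ± 17.98 to 18.5 ± 8.21 CPM, and the protease gene Ctse 3.15-fold. Genes that rose included the syntenin gene Sdcbp (from 268 ± 35.7 to 654 ± 146 CPM), the condensin subunit Smc4 (from 234 ± 14.9 to 529.6 ± 154) and Golt1b (2.47-fold). Of the replication genes, thymidylate synthase (Tyms) rose from 40.7 ± 10.2 to 88.5 ± 14.4 CPM and the replication protein Rpa2 from 26.0 ± 9.68 to 62.4 ± 8.05. The tight junction gene Cldn3 stood at 14.1 ± 6.92 CPM from 2 counts in all of shLuc, a ratio of pooled counts of 11.02 with a counting interval of 2.71 to 96.7.

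The 182 calls of limma among 12473 genes comprised 46 higher and 136 lower, a share of 25.3% higher, and 76 had an absolute log2 change of at least 1. That split moved with the scaling: 54.6% of 194 calls were higher after TMM scaling, 35.8% of 162 after quantile scaling and 36.4% of 220 without the mitochondrial genes. The count was 298 with edgeR, 50.7% of them higher, with 158 genes called by both, and 99 without shLuc replicate 5. The libraries did not overlap in 391 genes.

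DNA replication genes were higher than with shLuc, with 6 of 41 members higher and 0 lower (12 and 0 adjusted over the list alone), a median of 0.44 and an adjusted p of 4.4e-14. Against parental starved cells the list was not called with shSlug1 (median -0.07, camera adjusted p = 0.85), while shLuc lay below those cells (median -0.50). Members higher than with shLuc, besides Tyms and Rpa2, were the ribonucleotide reductase subunit Rrm2 (from 415 ± 48.5 to 614 ± 53.1 CPM) and the clamp loader subunit Rfc4 (from 241 ± 26.9 to 394 ± 97.7). Nucleotide synthesis rose, with 3 of 26 higher and 0 lower (4 and 0 adjusted over the list alone; median 0.21, adjusted p = 0.00056), among them Tyms and Rrm2, which are also in the replication list. Mesenchymal and EMT genes had 1 of 26 higher and 4 lower (1 and 5 adjusted over the list alone; median -0.41, or -0.36 with members at 0 put at their bound; adjusted p = 4.0e-04, adjusted p = 0.068 with an estimated correlation). The control library shLuc replicate 5 had the highest mean log2 level of the list (5.87, against 5.23 to 5.71 in the other shLuc libraries and 5.06 to 5.52 with shSlug1). Without it the median was -0.27 with 3 members lower (adjusted p = 0.0035, the highest of the 10 fits without 1 library). Vim (log2 -0.86, SE 0.12, adjusted p = 3.7e-06), Cald1 (log2 -1.005, SE 0.13, adjusted p = 4.4e-07) and the hyaluronan receptor Cd44 (log2 -0.77, SE 0.16, adjusted p = 0.0030; 0.062 without 3 libraries) were lower. Fn1, at 36.5 ± 9.86 against 66.1 ± 21.003 CPM (adjusted p = 0.023), lost its call without shLuc replicates 3 or 5 or shSlug1 replicates 1 or 4, with an adjusted p of up to 0.125, and also with no filter, after TMM or quantile scaling, with only the groups compared and after thinning (0.052 to 0.463). Cdh1, which Slug represses, had 41.2 ± 10.7 against 49.4 ± 5.84 CPM (log2 -0.29, SE 0.22, adjusted p = 0.65). The epithelial list of 33 had 1 higher and 2 lower (1 and 3 adjusted over the list alone; adjusted p = 0.36). Zeb1 had 51.4 ± 11.1 against 70.1 ± 10.8 CPM (adjusted p = 0.40) and Zeb2 20.6 ± 7.46 against 28.6 ± 7.68 (adjusted p = 0.67).

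ERK pathway output had 0 of 24 higher and 3 lower (1 and 6 adjusted over the list alone; median -0.33, adjusted p = 0.017, adjusted p = 0.060 with an estimated correlation). Cyclin D1 (Ccnd1) fell from 772 ± 68.3 to 481 ± 47.1 CPM beside Ereg. The call of the list was lost after TMM scaling (adjusted p = 0.065). In nuclear-encoded oxidative phosphorylation 1 of 70 was higher and 0 lower (3 and 0 adjusted over the list alone; median 0.18, adjusted p = 3.3e-10, adjusted p = 0.096 with an estimated correlation). The tRNA synthetases had 0 of 20 called, also adjusted over the list alone (median 0.06, adjusted p = 0.0070, adjusted p = 0.060 with an estimated correlation). The ribosomal proteins had 0 of 78, likewise (median 0.04, adjusted p = 0.026, adjusted p = 0.60 with an estimated correlation, and 0.32 after quantile scaling). There were 3 further lists that tested as lower. They were YAP targets (0 of 22 higher, 1 lower, the same over the list alone; Myof fell from 271 ± 28.7 to 179 ± 34.8 CPM; adjusted p = 0.034, adjusted p = 0.16 with an estimated correlation) and NRF2 targets (0 of 27 higher, 1 lower, the same over the list alone; Txn1 fell from 474 ± 72.0 to 312 ± 50.7; adjusted p = 0.037, adjusted p = 0.096 with an estimated correlation). The third was the mitochondrially encoded protein genes (0 of 7 called, 0 and 1 adjusted over the list alone; adjusted p = 0.037, adjusted p = 0.30 with an estimated correlation). After TMM scaling these 3 were not called (adjusted p = 0.075, 0.094 and 0.22). In all 10 lists were called, 5 in each direction. The calls of DNA replication and nucleotide synthesis held with an estimated correlation (adjusted p = 0.00018 and 0.015). Without single libraries the ribosomal, mitochondrial protein and NRF2 calls were lost in 5 of 10 fits each, the YAP call in 4 and the ERK call in 1, with shLuc replicate 5 among those of the first 4. The signs of median, mean and test differed for the NF-kB, TCA cycle and autophagy lists, none of them called. The rule for named genes also took Chaf1b and Spc24, which were higher, and Slc24a2, Lrrc75a, Efemp1, Kif1bp, Pbx2 and Gemin4, which were lower; each lost its call without 4 to 9 of the 10 single libraries.

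The second Slug hairpin was compared with the same shLuc libraries. Smc4 rose 2.93-fold from 234 ± 14.9 to 686 ± 56.5 CPM (SD, n = 5 each; log2 1.55, SE 0.14, adjusted p = 7.9e-12). The increase was 2.70-fold for Golt1b, to 71.2 ± 12.4 CPM, 2.69-fold for Rpa2, to 69.7 ± 21.7, 2.42-fold for Tyms, to 98.5 ± 25.1, and 2.20-fold for Sdcbp, to 588 ± 54.9. The NF-kB inhibitor gene Nfkbia rose from 114 ± 32.1 to 238 ± 29.3 CPM, the host transcript Snhg15 from 224 ± 47.6 to 464 ± 49.8 and the condensin subunit Ncapd3 from 46.6 ± 11.9 to 99.5 ± 28.8. The nuclear long noncoding RNAs Malat1 (from 2975 ± 413 to 1403 ± 271 CPM) and Neat1 (from 81.8 ± 14.7 to 35.2 ± 4.61) fell, as did Nfkbiz (2.39-fold), Tbcb (2.05-fold) and S100a7a (2.45-fold). The call of S100a7a was lost without 4 of the 10 single libraries, with an adjusted p of up to 0.198.

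Limma called 81 genes, 59 higher and 22 lower, 72.8% of them higher. After quantile scaling 54.3% of 70 were higher, without the mitochondrial genes 56.6% of 76, and with edgeR 65.9% of 138, with 79 genes called by both. The libraries did not overlap in 258 genes.

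DNA replication was also higher than in these shLuc libraries, with 6 of 41 higher and 0 lower (8 and 0 adjusted over the list alone, median 0.43, adjusted p = 1.3e-10). Because the shLuc libraries are shared, this is not independent of the result with shSlug1. Against parental starved cells the list was not called with shSlug2 (median -0.02, camera adjusted p = 0.72). The helicase subunit Mcm7 stood at 142 ± 20.5 against 84.2 ± 14.7 CPM (called except without shLuc replicate 4 or shSlug2 replicate 5, adjusted p up to 0.0545). Rfc4 stood at 400.4 ± 104 (called except without shLuc replicate 4 or shSlug2 replicate 4, adjusted p up to 0.115). Nucleotide synthesis had 2 of 26 higher and 0 lower (4 and 0 adjusted over the list alone; median 0.33, adjusted p = 1.1e-06). The amino acid response had 2 of 49 higher and 0 lower (5 and 0 adjusted over the list alone; median 0.22, adjusted p = 2.8e-07), led by the mitochondrial folate enzyme Mthfd2, which rose from 257 ± 20.9 to 496 ± 53.8 CPM. The tRNA synthetases had 1 of 20 higher and 0 lower (4 and 0 adjusted over the list alone; median 0.17, adjusted p = 4.0e-04). Mitosis had 1 of 40 higher and 0 lower, the same over the list alone (median 0.13, adjusted p = 0.022, adjusted p = 0.064 with an estimated correlation, and 0.064 without the mitochondrial genes). The kinase gene Plk1 stood at 155 ± 34.1 against 84.4 ± 14.3 CPM (adjusted p from 0.0010 to 0.0586 over the alternatives, the highest without shSlug2 replicate 4).

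Epithelial genes tested as lower with this hairpin, with 0 of 33 higher and 1 lower (0 and 2 adjusted over the list alone; median -0.29, adjusted p = 0.015). The member that passed was keratin 7 (Krt7), at 109.7 ± 30.5 against 193 ± 21.9 CPM (adjusted p = 0.0085; 0.089 without shSlug2 replicate 3). Mesenchymal and EMT genes had 0 of 26 called (0 and 1 adjusted over the list alone; median -0.19, or -0.16 with members at 0 put at their bound; adjusted p = 0.079). Camera on the recovered counts with edgeR called this list lower (adjusted p = 0.032), while camera in the limma fit with an estimated correlation gave 0.40. Vim had 332 ± 33.8 against 415 ± 106 CPM (log2 -0.29, SE 0.12, adjusted p = 0.41), Fn1 43.2 ± 7.82 against 66.1 ± 21.003 (adjusted p = 0.31) and Cdh1 38.7 ± 5.14 against 49.4 ± 5.84 (adjusted p = 0.68). Zeb1 had 57.03 ± 16.0 against 70.1 ± 10.8 CPM (adjusted p = 0.74), and Zeb2 33.4 ± 10.1 against 28.6 ± 7.68 (log2 0.21, adjusted p = 0.94), with -0.48 after thinning. The mitochondrially encoded list, with a mean share of 16.2% of the counts in this group against 19.8% in shLuc, had 0 of 17 called (0 and 5 adjusted over the list alone; median -0.36, adjusted p = 2.0e-07). Its protein genes had 0 of 7 (0 and 4 adjusted over the list alone; median -0.36, adjusted p = 1.9e-06). YAP targets had 0 of 22 called, also adjusted over the list alone (median -0.10, adjusted p = 0.030, adjusted p = 0.15 with an estimated correlation). Oxidative phosphorylation (0 of 70 higher, 1 lower, the same over the list alone; median 0.08, adjusted p = 0.018, adjusted p = 0.55 with an estimated correlation) and ribosomal proteins (0 of 78 called, also adjusted over the list alone; median 0.06, adjusted p = 0.015, adjusted p = 0.59 with an estimated correlation) tested as higher, and both turned to the other direction after quantile scaling (adjusted p = 0.78 and 0.53). Of 11 calls, 7 higher and 4 lower, 7 held with an estimated correlation: the amino acid response, tRNA synthetases, nucleotide synthesis, DNA replication, epithelial genes and both mitochondrially encoded lists. Without single libraries the ribosomal call was lost in 5 of 10 fits, that of oxidative phosphorylation in 4 and those of mitosis and YAP targets in 3 each. The signs of median, mean and test differed for the NF-kB, sterol synthesis and p53 lists, none of them called.

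With both hairpins 25 genes changed in the same direction, 18 higher and 7 lower, and 1 was called in opposite directions. The shared count was 62 with edgeR, 69 with DESeq2 and 15 after thinning. The chromatin remodeller gene Hells rose from 157 ± 18.02 CPM with shLuc to 267 ± 33.3 with shSlug1 and 309.8 ± 48.2 with shSlug2 (SD, n = 5 each). Rfc4, Smc4, Tyms, Rpa2, Golt1b and Sdcbp rose as given above. Besides Snai2, Phldb2 (809 ± 64.7 CPM with shLuc, 376 ± 56.6 and 527 ± 54.6 with the hairpins), Fbln2 (258 ± 67.5, 121 ± 16.6 and 157 ± 20.97), Ctse (217 ± 28.9, 68.9 ± 16.5 and 129.6 ± 13.9), the secreted chaperone Clu (879.8 ± 55.2, 667 ± 72.4 and 625 ± 29.0) and Malat1 (2975 ± 413, 1879 ± 215 and 1403 ± 271) fell. Malat1 stood at 1865 ± 306 CPM in parental starved cells, below shLuc (log2 0.68 for shLuc minus parental, limma adjusted p = 7.6e-06). Its level with shSlug1 was thus close to that of the parental cells. Of the 18 shared risen genes 4 belonged to the DNA replication list. The shSlug2 calls of Ctse and Fbln2 were lost without 3 and 1 single libraries (adjusted p up to 0.0674 and 0.0694). The shSlug1 call of Clu was lost with edgeR (adjusted p = 0.0772) and without shLuc replicate 5 or shSlug1 replicate 5 (up to 0.0984). It was also lost with only the groups compared, after TMM scaling, without 3 libraries and after thinning (0.090 to 0.401).

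Lists of these sizes drawn independently would share 0.457 genes. The log2 changes of the 12473 genes correlated with r = 0.521 across genes, which are not independent replicates, against 0.491 with groups simulated as unchanged, since both comparisons use the same shLuc libraries. The covariance was 0.191 against a simulated 0.146, a difference of 0.0459, and 68.2% of genes had the same sign against 66.3%. With the shLuc libraries divided between the hairpins, the covariance averaged 0.0417, r averaged 0.0794 and 5 to 11 genes were shared (mean 8.4).

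**Figure D3:**
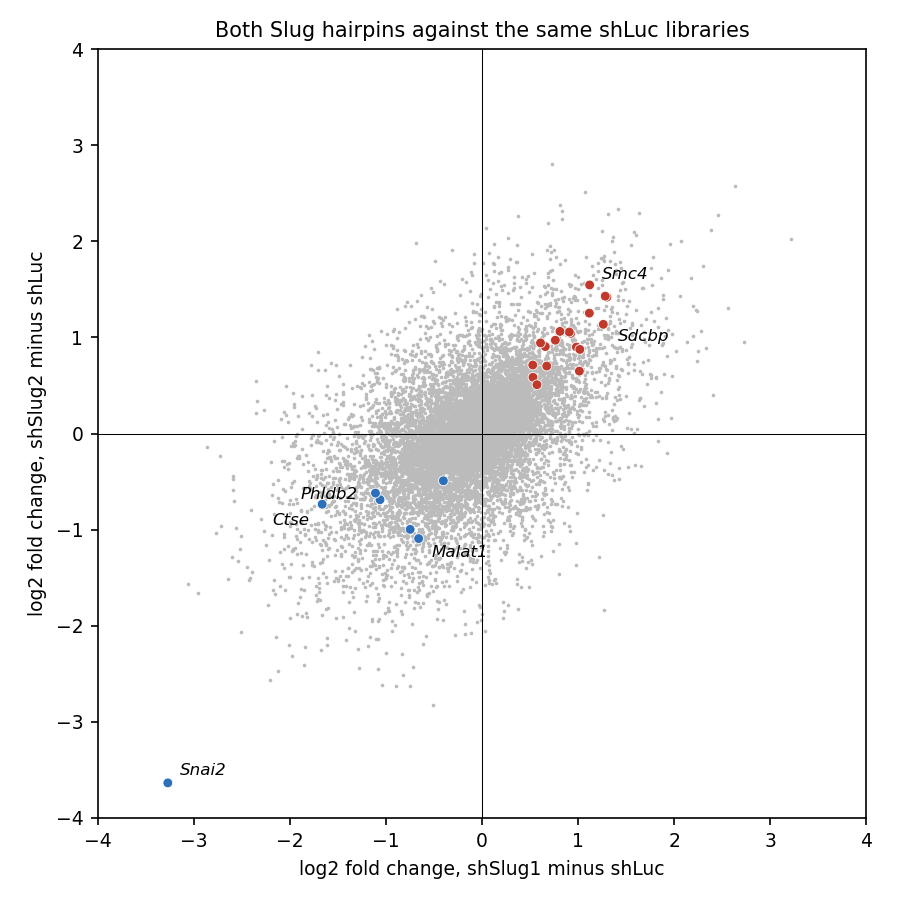
Log2 fold change against shLuc of the 12473 tested genes with shSlug1 (horizontal) and shSlug2 (vertical), with the 18 genes that rose with both in red and the 7 that fell with both in blue. Snai2 lies at -3.27 and -3.64, farther out than the other shared genes, and the grey cloud is tilted partly because both axes use the same shLuc libraries (simulated r = 0.491).

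Set against each other directly, the hairpins differed in 64 genes, 3 higher and 61 lower with shSlug1. Vim was lower with shSlug1, at 225 ± 20.7 against 332 ± 33.8 CPM (log2 -0.56, SE 0.12, adjusted p = 0.0083). Also lower were Cald1 (351 ± 96.9 against 562 ± 40.4; adjusted p = 0.00078), the TCA cycle subunit Idh3b (33.8 ± 6.03 against 93.3 ± 22.9), the mitochondrial import receptor Tomm70a (64.4 ± 31.1 against 152 ± 33.1), Napg (4.13-fold), the kinase gene Cdk13 (3.49-fold), Zrsr2 (2.53-fold) and Marcksl1 (2.50-fold). The call of Vim was lost after TMM or quantile scaling and those of Vim and Cald1 without 3 libraries (adjusted p up to 0.132 and 0.0805). Ereg was 2.65-fold lower with shSlug1 (adjusted p = 0.013; up to 0.0646 without shSlug2 replicates 2 or 3). The carbonic anhydrase gene Car2 (131 ± 24.6 against 56.7 ± 8.49 CPM), Cox6c (501 ± 59.0 against 342 ± 41.5) and Aldoa (1185 ± 132 against 855 ± 80.2) were higher, and their calls were lost without 6, 1 and 3 of the 10 single libraries (adjusted p up to 0.0826, 0.0584 and 0.071). Fancc, at 2.61 ± 3.71 against 11.9 ± 3.54 CPM, lost its call without 8 of them. The count was 90 with edgeR, 28.9% higher, 40 after TMM scaling, 22.5% higher, 47 without mitochondrial genes, 21.3% higher, against 4.7% here. It was 37 without shSlug2 replicate 4. Both limma and edgeR called 46 genes. The libraries did not overlap in 259 genes.

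Among the lists, oxidative phosphorylation (1 of 70 higher, 0 lower, the same over the list alone; adjusted p = 6.4e-05), the mitochondrially encoded genes (0 of 17 called, 1 and 0 adjusted over the list alone; adjusted p = 0.0018) and their protein genes (0 of 7 called, also adjusted over the list alone; adjusted p = 0.046) tested as higher with shSlug1. The amino acid response (0 of 49 called, 0 and 1 adjusted over the list alone; adjusted p = 0.0048), glutamine metabolism (0 of 21 called, 0 and 2 adjusted over the list alone; adjusted p = 0.021) and mesenchymal genes (0 of 26 higher, 2 lower, 0 and 3 adjusted over the list alone; adjusted p = 0.032) tested as lower. With an estimated correlation 0 of these 6 calls held, with adjusted p = 0.29, 0.14, 0.30, 0.14, 0.14 and 0.26 in the order given. The EMT call was lost under each of 5 other scalings and library choices, and in 4 of 10 fits without 1 library, as were the calls of the mitochondrial protein genes in 6 and of glutamine metabolism in 1. DNA replication was not called between the hairpins (median 0.04, adjusted p = 0.15). The signs of median, mean and test differed for the autophagy, NRF2 and ribosomal lists, none of them called.

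Whether genes changed by glutamine starvation moved back when Slug was knocked down was asked with the 1341 risen and 1458 fallen genes of the parental comparison, which shares no library with the hairpin comparisons. With shSlug1 the median log2 change was -0.06 for the risen and -0.03 for the fallen genes, against -0.09 over all genes (adjusted p = 0.52 and 0.296; 0.81 and 0.72 with an estimated correlation). With shSlug2 it was 0.06 and 0.03 against 0.01 over all genes (adjusted p = 0.061 and 0.787; 0.63 and 0.86 with an estimated correlation). The share of genes whose sign was opposite to starvation was 56.7% of the risen and 47.4% of the fallen genes with shSlug1, where 57.9% and 42.1% of all genes had those signs. With shSlug2 it was 43.1% and 52.4%, against 49.5% and 50.5%. The adjusted p for the risen genes with shSlug2, whose median lay in the direction of starvation, ran from 0.025 to 0.28 when single libraries were left out, and was under 0.05 in 13 of 25 such fits.

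A score per library, the mean log2 level of the risen minus that of the fallen genes, was -1.02 ± 0.0188 in complete medium and 1.90 ± 0.229 in starved cells (SD, n = 5 each), the libraries that defined it. It was 1.24 ± 0.0530 with shLuc, 1.17 ± 0.0341 with shSlug1 and 1.27 ± 0.0414 with shSlug2. The difference from shLuc was -0.07 for shSlug1 (exact permutation p = 0.0397, adjusted p = 0.0595 over 3 tests) and 0.04 for shSlug2 (exact permutation p = 0.254, adjusted p = 0.254). The genes of the score were chosen in the parental starved libraries, so the lower score of all 3 hairpin groups does not test for a weaker response to starvation. The gene-wise log2 changes of starvation and knockdown had r = -0.031 for shSlug1 and 0.012 for shSlug2 across 12473 genes, which are not independent replicates. Relative to parental cells in complete medium, the median log2 change in starved shLuc cells was 1.09 for the risen genes (1.08 in starved parental cells) and -0.93 for the fallen ones (-1.40). No shLuc cells were measured in complete medium, so the shLuc values mix starvation with the difference between the lines.

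**Figure D4:**
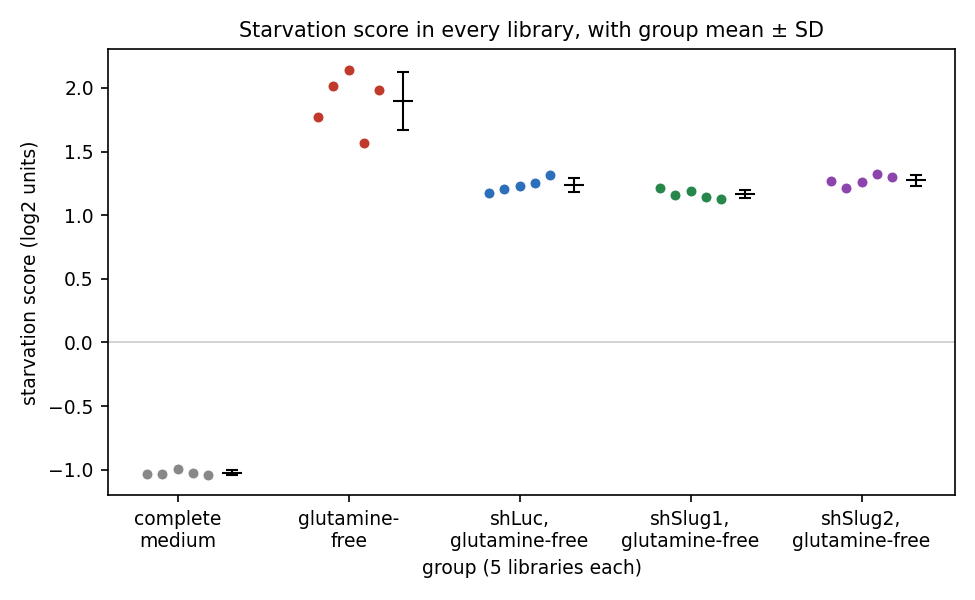
Starvation score (log2 units) of every library by group, with the group mean ± SD beside the points. The complete medium libraries lie near -1.02 and the starved parental ones near 1.90, and the 3 hairpin groups lie close together between them at 1.24, 1.17 and 1.27.

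ShLuc cells and parental cells, both starved, may differ by the vector, the selection, the handling of a derived line and the preparation of the samples. These cannot be told apart here. The comparison shows how far shLuc, the reference of the Slug hairpins, stood from the parental cells. The keratin gene Krt18 was higher in shLuc cells, at 5087 ± 540.3 against 1804 ± 277 CPM (SD, n = 5 each). So were the polarity gene Crb3 (4.04-fold), Krt19 (1.77-fold) and the tumour suppressor gene Cdkn2a (309 ± 97.3 against 103 ± 27.7 CPM). Fn1 was lower, at 66.1 ± 21.003 against 324 ± 50.2 CPM (log2 -2.32, SE 0.21, adjusted p = 1.6e-13), as were Vim (415 ± 106 against 761 ± 96.2; log2 -0.90, SE 0.12, adjusted p = 4.7e-08), the cystine transporter Slc7a11 (4.40-fold) and Atf4 (195 ± 29.4 against 429.6 ± 39.7). Zeb2 had 28.6 ± 7.68 against 64.0 ± 21.8 CPM (adjusted p = 0.031), a call lost without 6 of the 10 single libraries (adjusted p up to 0.0943) and after quantile scaling. Limma called 2942 genes, 1680 higher and 1262 lower, 57.1% of them higher, and edgeR 3006, with 2592 called by both. Without the mitochondrial genes 47.0% of 2943 calls were higher. The libraries did not overlap in 1819 genes.

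Nuclear-encoded oxidative phosphorylation was the most uniform list, with 46 of 70 higher and 1 lower (49 and 1 adjusted over the list alone; median 0.54, adjusted p = 2.0e-18), by Ndufa5 (2.22-fold), Ndufa6 (2.11-fold), Cox6b1 (2.05-fold) and Uqcr10 (1.83-fold). The p53 target list had 7 of 20 higher and 0 lower, the same over the list alone (adjusted p = 0.0042), including Bax (2.33-fold), Plk2 (2.11-fold) and Cdkn1a (2.43-fold). It also holds Cdkn2a (3.01-fold), a regulator rather than a target of p53, so the count is not one of targets alone. The activity of p53 was not measured. Epithelial genes had 11 of 33 higher and 3 lower (11 and 5 adjusted over the list alone; median 0.74, adjusted p = 0.0080). The amino acid response was lower, with 5 of 49 higher and 19 lower (5 and 22 adjusted over the list alone; median -0.35, adjusted p = 0.00048), though Nupr1 was 2.90-fold higher. The tRNA synthetases had 0 of 20 higher and 10 lower (0 and 12 adjusted over the list alone; adjusted p = 6.4e-06), among them Iars (3.25-fold), Gars (2.06-fold), Vars (2.06-fold) and Rars (1.91-fold). Glutamine metabolism and transport had 0 of 21 higher and 10 lower (0 and 12 adjusted over the list alone; median -0.69, adjusted p = 3.0e-05). The glutamine transporters Slc38a2 and Slc1a5 were 2.31-fold and 4.51-fold lower. Nucleotide synthesis had 1 of 26 higher and 9 lower (1 and 12 adjusted over the list alone; adjusted p = 0.0020). Paics was 2.68-fold and Mthfd1 3.74-fold lower, and Rrm2 was 1.61-fold higher. DNA replication had 2 of 41 higher and 13 lower (3 and 14 adjusted over the list alone; median -0.50, adjusted p = 0.00034). Pcna was 2.62-fold, Ccne2 2.17-fold and Mcm7 1.88-fold lower.

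Mesenchymal and EMT genes had 2 of 26 higher and 10 lower, the same over the list alone (median -0.56, adjusted p = 0.00048, adjusted p = 0.0501 with an estimated correlation). The integrin gene Itgb1 was 1.79-fold and the receptor kinase gene Axl 2.11-fold lower. NRF2 targets had 2 of 27 higher and 8 lower (4 and 9 adjusted over the list alone; adjusted p = 0.025, adjusted p = 0.053 with an estimated correlation). Txnrd1 was 2.51-fold and Abcc1 2.88-fold lower, and Prdx1 was 1.63-fold higher. For the mitochondrially encoded genes 1 of 17 was higher and 6 lower (3 and 7 adjusted over the list alone). Their median was -0.12 and their mean 0.04 while the test gave lower (adjusted p = 0.028, adjusted p = 0.26 with an estimated correlation). The protein genes among them had 0 of 7 higher and 4 lower (1 and 4 adjusted over the list alone; adjusted p = 0.026, adjusted p = 0.26 with an estimated correlation), with mt-Nd5 1.77-fold lower. Of the 12 calls, 3 higher and 9 lower, the other 8 held with an estimated correlation. Without shLuc replicate 1 both mitochondrial calls were lost, and without starved replicate 3 that of all mitochondrially encoded genes (adjusted p up to 0.0983). Median, mean and test also differed in sign for the ERK, unfolded protein, sterol, mitosis, autophagy and ribosomal lists, none of them called.

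The genes taken for their large fold changes in this comparison had few counts. Higher in shLuc were Sgcz, a sarcoglycan gene, at 28.1 ± 10.4 against 3.34 ± 4.63 CPM, the calcium channel gene Cacna1c at 15.2 ± 2.49 against 1.45 ± 3.25. Veph1 stood at 11.8 ± 4.63 CPM against no count, which is at least 5.51-fold with the floor at 3 counts over the group. Med12l, Pard3b, Mall and Cntnap5b each rested on 1 count in parental cells, with ratios of pooled counts of 20.007 (interval 3.25 to 824), 19.1 (3.09 to 789.8), 22.6 (3.72 to 927) and 23.5 (3.87 to 962). Dlc1 rested on 2, with 11.3 (2.83 to 98.3). Most of these genes are long: Sgcz spans 1139 kb, Pard3b 1003 kb, Cntnap5b 713 kb and Cacna1c 609 kb, whereas Mall spans 25.5 kb. Lower in shLuc were Zfp770 (8.54-fold), Fsd1l (8.11-fold), the replication checkpoint gene Clspn (7.69-fold), Mllt6 (6.46-fold) and Ankrd13b (5.67-fold). The BMP antagonist gene Grem1 and Bicdl1 each had 1 count in shLuc, with pooled ratios of 24.1 (3.88 to 998) and 20.7 (3.27 to 862), and Def8 had 3, with 9.20 (2.79 to 47.7).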

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

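The tests of a length-dependent background and of a low level in the shLuc libraries were chosen only after the result was seen, as were the thinned, mitochondria-free and reduced sets of libraries that other tests use and the reading of the nuclear RNA test.

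Long genes with few counts were higher in shLuc than in parental starved cells: of 617 such genes of at least 200 kb, 25.1% were called higher, against 3.92% of 3083 genes under 50 kb. The median log2 difference between the classes was 1.30, which fits a background that grows with gene length. Such a background may be genomic DNA, since 542 olfactory and vomeronasal receptor genes, most of them silent outside sensory tissue, had 38.9 counts per Mb in shLuc, or 115% of the density over the long genes. In parental starved cells the densities were 14.3 over receptor and 17.1 over long genes, so that the densities were also similar there. The comparison within shLuc thus does not account for the excess. Scaled by depth, the density in shLuc was 2.36-fold that in parental starved cells over receptor genes and 1.72-fold over long genes. Depth alone is argued against by a difference of 1.26 after thinning. Of the nuclear transcripts Neat1 was lower (-1.36), which met the bound set beforehand against nuclear RNA. Malat1 rose by 0.68, as nuclear RNA predicts. With shSlug2 the long genes held 0.58% of the counts, as with shLuc (0.58%), against 0.33% in parental starved cells. With that hairpin Malat1 (1403 against 1865 CPM) and Neat1 (35.2 against 211 CPM) were both below parental starved cells. These values argue against nuclear RNA in the shSlug2 group. For the long genes in shLuc, where the transcripts disagreed, nuclear RNA stays open. A change of these genes in the derived line stays open and was not tested: the receptor density would give 27.1 CPM for Sgcz (28.1 measured), 17.0 for Cntnap5b (16.2) and 14.5 for Cacna1c (15.2), but 23.9 for Pard3b (13.3), 7.44 for Med12l (14.1), 9.16 for Dlc1 (15.9), 5.79 for Veph1 (11.8) and 0.607 for the short gene Mall (15.6).

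DNA replication genes were higher with both Slug hairpins than with shLuc (medians 0.44 and 0.43). A low level in the shLuc libraries is a candidate explanation: against parental starved cells the list had a median of -0.068 with shSlug1 and -0.02 with shSlug2, and of -0.50 with shLuc. Members differed, with 6 of 41 called higher and 5 lower with shSlug1, 6 and 9 with shSlug2, and 2 and 13 with shLuc. Rrm2, which rose with shSlug1, was among the 2 (415 against 257 CPM), so a low shLuc level does not account for it. The mitochondrial share of the counts is argued against by medians of 0.36 and 0.46 without the mitochondrial genes. Chance deviations of single shared control libraries are argued against by medians above 0.2 for both hairpins in 20 of 20 divisions of the shLuc libraries. Since every division draws on the same shLuc line, this test cannot address a low level in all of its libraries. An effect of Slug on these genes stays open, since shLuc was the only control hairpin.

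With the first Slug hairpin fallen genes outnumbered risen ones, at 25.3% of 182 calls higher. The share was 54.6% of 194 calls after TMM scaling, and 44.4% of 133 without shSlug1 replicates 4 and 5, whose mitochondrial share was high, while leaving out other pairs of that group gave 12.7% to 25.7%. Both the scaling and these libraries could therefore account for the excess of fallen genes. Depth cannot be told apart from it, since only 75 calls were left after thinning, 30.7% of them higher. A real excess of fallen genes was not tested in another way.

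Single libraries stood far from the other 4 of their group, by a gap over the range above 0.71, in 28 of 441 groups of 5 values tested. Chance gives about 1 in 20. Where a gene was seen in only 1 library of a group, the gap over the range is 1 whatever its count. Those cases, named below as the only counts of a gene, therefore do not show a deviant library. Replicate 5 of shLuc had 15386 genes detected against 13717 to 14184 in the others, and it had the highest Vim (602 CPM against at most 395.9), Fbln2 (374 against at most 253), Itgb1 (369 against at most 291) and Axl (179 against at most 130.2) of its group. In complete medium, replicate 3 had the highest Snai2 (17.1 CPM against at most 5.86) and Prdx1 (1072 against at most 849.5). In starved cells, replicate 3 had the highest Atf4 (498 CPM) and the only Mall count (6.30), and replicate 2 the highest Got1 (193) and the lowest Top2a (146). Replicate 4 of the starved group, the deepest library, held the only counts of Med12l, Pard3b and Cntnap5b (1.82 CPM each), Dlc1 (3.64) and Cacna1c (7.27). In shLuc, Cldn3 was seen only in replicate 4 (6.33 CPM), Grem1 only in replicate 4 (3.16) and Bicdl1 only in replicate 3 (3.10). There Med12l was highest in replicate 4 (22.2) and Pard3b in replicate 2 (19.2), and Neat1 was lowest in replicate 1 (55.6) and Mthfd2 in replicate 3 (220.2). With shSlug1, Phldb2 was highest in replicate 1 (477 CPM) and Txn1 in replicate 2 (401). With shSlug2, Rfc4 (580.1 CPM) and Aldoa (994) were highest in replicate 4 and Idh3b (133) in replicate 5.

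The effect of the hairpins differed in 64 genes by the direct test of shSlug1 against shSlug2 with limma. Among the named ones the log2 difference was 1.18 for Car2, 0.55 for Cox6c and 0.47 for Aldoa. It was -2.49 for Fancc, -2.03 for Napg, -1.70 for Cdk13, -1.43 for Idh3b, -1.43 for Ereg, -1.34 for Tomm70a, -1.33 for Zrsr2, -1.31 for Marcksl1 and -0.56 for Vim.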

How the results depend on the processing

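Thinning, the set without mitochondrial genes, the fit without 3 libraries and the estimated correlation as an alternative were tests chosen after the data were seen. Snai2 kept its direction and its call in every alternative that gave an adjusted p (DESeq2 gave none for shSlug2). Of 219 gene results that the naming rule took and the test called, 4772 of 4997 values under the alternatives kept direction and call, 224 kept the direction only and 1 turned, and thinning ended the most calls, 34. With 1 count worth 1.82 to 6.30 CPM, genes under about 10 CPM rest on a few counts per library, and the simulated comparisons recovered 26% to 44% of 2-fold changes, so a missing call is not evidence of no change. In the simulated starvation comparison 15 of 117 limma calls were false.

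The values that moved are grouped by setting, and the cause was not tested except where fewer counts, genes, libraries or a larger correlation make calls fewer. The starvation gene sets are given as medians relative to all genes (0.03, 0.07, 0.06 and 0.02 for risen and fallen genes with shSlug1, then shSlug2). No filter: -0.062 and -0.017 for the risen and fallen sets with shSlug1. A minimum of 20 CPM: 6 lists called with shSlug1, and -0.0063 for the fallen set with shSlug2. TMM: 40 genes and 3 lists between the hairpins. Quantile scaling: 2 lists between the hairpins, -0.024 for the risen set with shSlug1, -0.0062 for the fallen set with shSlug2, 0.016 for Cdh2 and 0.0065 for mt-Nd1 under starvation. Only the groups compared: 121 genes with shSlug1, and -0.00025 for the fallen set with shSlug2. EdgeR: 298 genes with shSlug1, 138 with shSlug2, 62 with both, 0.52 for Cdh2 and -0.012 for the fallen set with shSlug2. DESeq2: 140 genes with shSlug2, 69 with both, and -0.0047 for that set. Thinning: 1642 genes under starvation, 75 with shSlug1, 42 with shSlug2, 15 with both, 28 between the hairpins, 1610 for shLuc against parental, 5 lists with shSlug1 and 3 between the hairpins, and -0.48 for Zeb2 with shSlug2. Without mitochondrial genes: 1 list between the hairpins. Without 3 libraries: 34 genes between the hairpins. Estimated correlation: 8, 2, 7 and 0 lists for starvation, shSlug1, shSlug2 and between the hairpins.

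Leaving out single libraries gave 2484 to 2720 genes for starvation, 99 (without shLuc replicate 5) to 197 with shSlug1, 57 to 80 with shSlug2, 18 to 28 with both, 37 (without shSlug2 replicate 4) to 79 between the hairpins and 2537 to 2912 for shLuc against parental. Lists called were 18 to 19, 6 (without shLuc replicate 5) to 10, 8 to 12, 4 to 7 and 10 to 12 in the order of the report's single comparisons. Snai2 ran from 3.24 to 3.71, -3.50 to -2.66 and -3.89 to -3.11. The sets ran from 0.02 to 0.04, 0.05 to 0.09, 0.035 (without shSlug2 replicate 4) to 0.069 (called in 13 of 25 fits) and -0.0031 (without shLuc replicate 5) to 0.034.

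Same-numbered libraries of the compared groups deviated together little, if at all (correlations of -0.0499 to 0.0264, none over 0.1). A library correlated best with its own number in 3, 0, 0, 0 and 4 of 5 pairs. Counting noise at this depth can hide a shared deviation, so a pairing by number cannot be excluded, least of all in the first and last comparison. With the replicate block the counts were 2774, 182, 76, 57 and 2930 genes, 24 with both hairpins and 12 lists with shSlug2.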

Other observations

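The comparisons of each Slug hairpin with the parental line were tests chosen after the result was seen, and the splits were planned. Measured against parental starved cells, the mesenchymal and EMT list of 26 tested as lower in all 3 hairpin lines. The median log2 difference was -0.56 with shLuc (2 members higher, 10 lower; camera adjusted p = 0.00048), -1.01 with shSlug1 (3 higher, 10 lower; adjusted p = 3.1e-05) and -0.73 with shSlug2 (4 higher, 9 lower; adjusted p = 0.00022). With an estimated correlation the adjusted p was 0.0501, 0.033 and 0.045 in that order, so the shLuc call was lost. The mean log2 level of the DNA replication list was 6.01 ± 0.0989 in complete medium (SD, n = 5 libraries each), 5.53 ± 0.141 in starved parental cells, 5.04 ± 0.102 with shLuc, 5.51 ± 0.116 with shSlug1 and 5.43 ± 0.0849 with shSlug2. Over the receptor genes described above, the density was 5.84 ± 1.89 CPM per Mb in complete medium and 9.60 ± 2.38 in starved parental cells, against 23.8 ± 7.40 with shLuc, 17.0 ± 7.45 with shSlug1 and 21.8 ± 7.37 with shSlug2.

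Chance assignment of the libraries was checked with 100 splits of each pair of groups, the real one included. For the counts of genes no other split reached the real one. For the counts of lists other splits came close to the real one, matched it or passed it. The check does not exclude chance. Its smallest possible share is 1 of 100, and splits that mix differing groups have a wider spread and so tend to call fewer genes. Whether the replicates were separate cultures is also not given. For starvation the real split gave 2799 genes and 18 lists, and the highest other 442 and 15, so that 1 of 100 splits reached each. With shSlug1 it gave 182 genes and 10 lists against 13 and 9, and between the hairpins 64 genes and 6 lists against 3 and 6, where 2 splits reached the lists. With shSlug2 it gave 81 genes and 11 lists against 2 and 12, where 4 splits reached the lists. For shLuc against parental starved cells it gave 2942 genes and 12 lists against 1126 and 13, where 3 splits reached the lists. With both hairpins 25 genes were shared, and at most 1 in the other splits of the 15 libraries.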
